A study of Mus musculus with 24 samples.

How the data were processed

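RNA m6A was measured in 24 samples, of which 12 were immunoprecipitated with an m6A antibody and 12 were the matching inputs. The 12 immunoprecipitated samples have a peak list each and are analysed here; the inputs were not analysed here. Per the labels' protocols, oocytes and embryos came from superovulated 8-week-old mice, cumulus cells were removed by pipetting (GV) or dispersed with hyaluronidase (MII), the zona pellucida was removed with acid, ribosomal RNA and DNA were depleted, and RNA was sheared by sonication, with a small part kept as input. Pools held 49 GV oocytes, 100 or 110 MII oocytes, 51 or 100 8-cell embryos, and 100 zygotes, 2-cell embryos or blastocysts. Embryos were collected 27 to 28 h (zygote), 39 to 43 h (2-cell), 68 to 70 h (8-cell) and 92 to 94 h (blastocyst) after injection of chorionic gonadotropin.

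Per the submitters' processing notes, the mm10 build and the tools FastQC 0.11.8, cutadapt 1.8.1, HISAT2 2.1.0, SAMtools 1.9, deepTools 3.2.0, bedtools 2.28.0 and MACS2 2.1.2 were used; their settings are not given in the sources used here. The peak names in the deposited files show that the authors called peaks for each immunoprecipitated library against the input of the same stage and replicate, so replicates were not pooled. The deposited lists give for each summit the authors' score (10 times the −log10 q-value, rounded down, in 99.9993% of lines), fold enrichment (a ratio) and −log10 p-value and −log10 q-value. The lowest −log10 q-value was near 1.3 in each list, the authors' threshold as the deposited values show it. These values were used only to rank or filter peaks and to describe single peaks. The lists held 143579 summits; summits that share an interval were collapsed to 1 peak with the best q-value, which left 113764 peaks of 200 to 3754 bp. No read counts are given, so depth is unknown, and the length of a list can move with it.

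Genes were taken from a RefSeq table of GRCm38.p6, whose primary assembly is that of mm10. It holds 49943 entries on chromosomes 1 to 19, X and Y, 21887 of them protein-coding, with gene starts and ends but neither strand nor exons. For this reason the planned test by exon overlap was replaced by overlap with the gene body of at least 1 bp, and the planned transcript features by 3 classes set by the peak midpoint: protein-coding gene bodies, other genes only, and intergenic. The share of peaks within 2000 bp of either gene end took the place of the stop codon window, and the planned motif test, which needs a genome sequence, was not run. A gene body includes introns, and 3.37% of the peaks in protein-coding genes touch several. Intergenic here means outside the genes of this table.

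The stages were grouped before the data were examined into a maternal phase (GV oocyte, MII oocyte, zygote; 6 libraries) and an embryonic phase (2-cell, 8-cell, blastocyst; 6 libraries). Peak sets were compared by the Jaccard index of base pairs, tested exactly over all pairings of the libraries and the 10 splits of the stages. Values per library were compared by an exact two-sided permutation test over all splits of the 12 libraries 6 against 6, whose smallest p is 0.00216. Genes were tested with Fisher's exact test on the number of marked libraries, adjusted by Benjamini-Hochberg at 0.05 over genes marked in 5 to 7 libraries, the totals that can reach an unadjusted p of 0.05. Genes gained or lost between consecutive stages were counted without a test. For 14 gene lists (395 symbols, 391 found in the table), the share of members marked minus the share of all 9903 background genes marked was tested per library, adjusted over 13 lists; a list needed 5 members in the background. The background is the protein-coding genes marked in at least 1 library.

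Genes named in the text follow a rule fixed before the data were examined: 12 per phase with the largest difference in marked libraries, ties by the mean percentile of the best peak; 4 gained and 4 lost per step by the same percentile; up to 4 per list; and 5 marked in all 12 libraries. Gene models without a symbol were skipped. The members of the writer complex outside that rule were named after their values were seen.

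The gene test was tested on simulated marks for 9903 genes. With 200 changed genes it called none after adjustment, since each p is bounded by 0.00216 and few genes reach it, although 88% of those with marking probabilities of 95% against 5% had an unadjusted p under 0.05. With 1200 changed genes it recovered 53.3% of that size and 12% of those with 80% against 10%, with 0 false calls. A count of 0 after adjustment therefore does not exclude a group of changed genes. When stages varied with no phase effect, 0 genes were called after adjustment and 176 had an unadjusted p under 0.05. In that simulation each stage was drawn on its own, without the likeness of neighbouring stages seen in the real lists. With 200 or 1200 changed genes each library was drawn independently. These counts of false calls therefore do not cover likeness between stages. The list test passed 5.5% of 400 simulated lists without an effect, but there each library was drawn independently, with no likeness of replicates or stages. On the real marks, 37.3% of 1000 random lists of 20 genes reached an unadjusted exact permutation p under 0.05. The overlap functions gave the same values as bedtools 2.31.1 on simulated intervals.

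Alternatives were the same number of top peaks per library (6914), a −log10 q-value at or above 20.2 (the median of all lists), an overlap of 100 bp, a reciprocal overlap of 50%, each library left out in turn, a replicate block, oocytes against embryos, and stages permuted. Added after the data had been seen were peaks inside 1 gene only, genes under 50000 bp, peaks within 2000 bp of a gene end, peaks with a fold at or above the median of their own library, and random gene lists. A contrast of 8-cell and blastocyst libraries with the others, run after the shares of peaks had been seen, was dropped, since it grouped the libraries by the outcome it tested. Exact binomial intervals at 95% cover counting error only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.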

Results

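N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, was mapped in C57BL/6N mouse oocytes and preimplantation embryos by a low-input version of immunoprecipitation of methylated RNA followed by sequencing. There were 6 stages: oocytes at the germinal vesicle (GV) stage, oocytes arrested at metaphase II (MII), zygotes, 2-cell embryos, 8-cell embryos and blastocysts. Each stage had 2 biological replicates, per the series' design text, each a pool of 49 to 110 oocytes or embryos with its own list of peaks of antibody-bound over input RNA. The lists held between 6914 (zygote replicate 1) and 11959 (GV oocyte replicate 2) peaks, 113764 in all. Read depth was unknown, and the 12 input libraries were not analysed here, so a gene without a peak can be unmethylated, weakly expressed or below the detection limit of its library. GV oocytes, MII oocytes and zygotes, whose RNA is mostly inherited from the growing oocyte, are called the maternal phase here, and the 3 later stages the embryonic phase. A protein-coding gene with a peak over its body is called marked.

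The first comparison asked whether replicates of a stage shared their m6A peaks and how the peak sets changed through development. GV oocyte replicates shared the most sequence, with a Jaccard index (shared over combined base pairs) of 0.707, and blastocyst replicates the least, with 0.368. MII oocytes and zygotes, on either side of fertilisation, overlapped by 0.556 on average, more than 4 of the 6 stages overlapped between their own replicates. From zygote to 2-cell, when the maternal RNA is cleared and the embryonic genome becomes active, the mean overlap was 0.235, and from 2-cell to 8-cell 0.225. The 8-cell and blastocyst lists overlapped by 0.354. The 2-cell lists overlapped by 0.173 with those of blastocysts, and by 0.215 and 0.232 with those of GV and MII oocytes. On these means they thus did not group more closely with the later stages than with the maternal ones, but the replicates differed. Replicate 2 overlapped the 8-cell libraries by 0.255 and 0.258, above its 0.223 to 0.240 with the maternal libraries. Replicate 1 overlapped the 8-cell libraries by 0.194 and 0.194, below its 0.204 to 0.241 with the maternal libraries. The mean over the 6 replicate pairs was 0.520, against 0.249 between stages, and over all ways of pairing the libraries 2 gave a mean as large, the real one included (exact permutation test, one-sided, p = 0.000192). The other had a higher mean: it paired MII oocyte replicate 1 with zygote replicate 2 (0.632) and MII oocyte replicate 2 with zygote replicate 1 (0.539). The true replicates overlapped by 0.600 (MII oocyte) and 0.523 (zygote), so overlap did not tell these stages apart. Different stages of the same phase overlapped by 0.359 and stages of different phases by 0.176. That difference of 0.184 was the largest of the 10 splits of the stages (next 0.0728; exact permutation p = 0.1, the smallest that 3 stages against 3 allow).

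**Figure D1:**
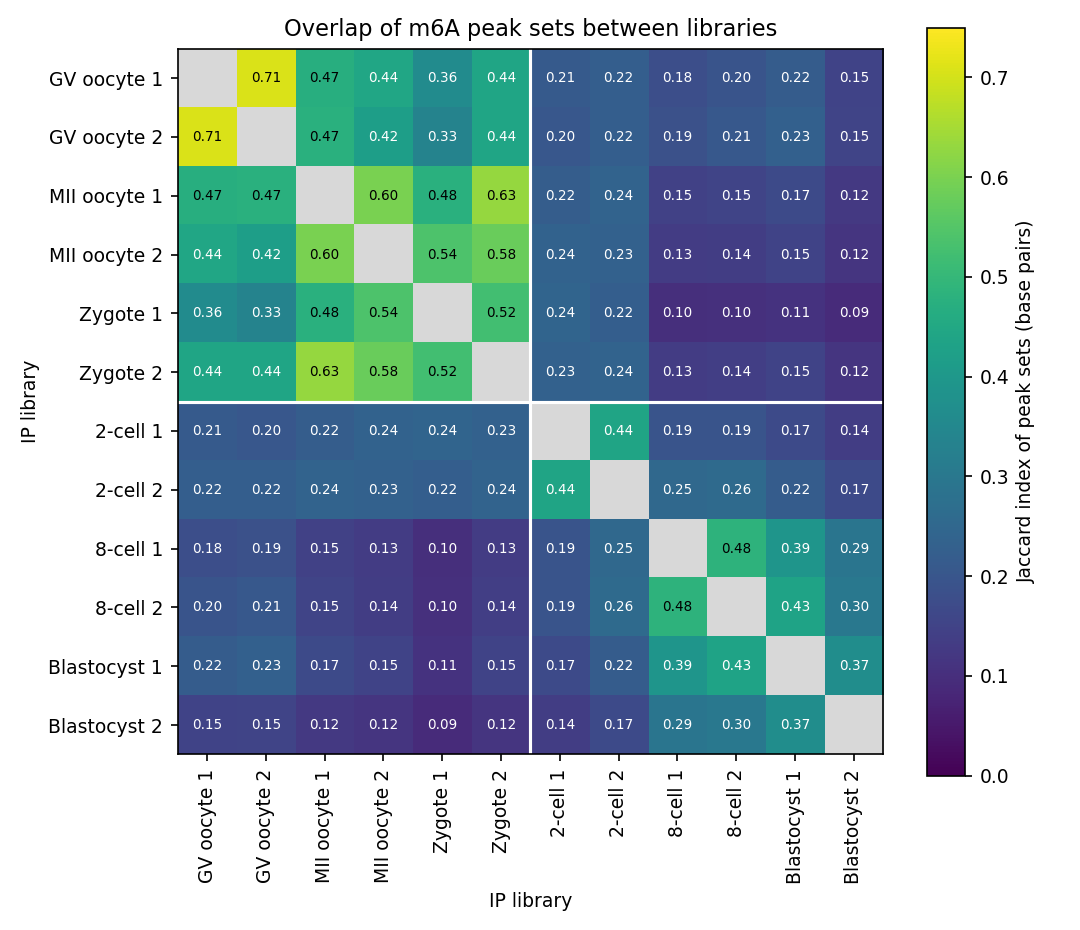
Jaccard index (base pairs) between the peak sets of the 12 immunoprecipitated libraries, on both axes in order of development, with white lines between the maternal and the embryonic phase and the diagonal left grey. Replicate pairs range from 0.368 in blastocysts to 0.707 in GV oocytes, and MII oocytes and zygotes overlap by 0.556 on average.

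Some transcripts were marked at every stage. Of the 828 protein-coding genes marked in all 12 libraries, the 5 with the highest-ranking peaks were Trim30a, Pabpn1 (the nuclear poly(A)-binding protein), Ppig (a nuclear cyclophilin), Phf3 and Tent4b (a non-canonical poly(A) polymerase). The best Pabpn1 peak, in zygote replicate 2, lay at mm10 chromosome 14, 54897871 to 54898451, 767 bp from a gene end, with 11.5-fold enrichment as given by the authors. The 6 libraries of the maternal phase held 9951 ± 1786 peaks (mean ± SD) and those of the embryonic phase 9010 ± 585 (exact two-sided permutation test, p = 0.247). The number of marked genes was 4292 ± 781 and 4513 ± 571 (n = 6 each, exact permutation p = 0.602). Without zygote replicate 1, the shortest list, the peak numbers differed by 1548 (exact permutation p = 0.0173). Without any other single library the exact permutation p was 0.203 to 0.481. Among peaks with a score at or above the median of all lists, the peak numbers differed by 2577 (exact permutation p = 0.00866). The median −log10 q-value was 20.4 to 33.3 in the maternal lists and 10.7 to 18.0 in the embryonic ones. That cut-off therefore removes more of each embryonic list, and read depth was unknown. Median fold was 4.59 to 5.99 in the maternal lists and 5.68 to 6.79 in the embryonic ones.

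Peaks outside annotated genes were abundant up to the 2-cell stage and scarce afterwards. They made up 21.2% ± 0.742 of the peaks in GV oocytes, 20.9% ± 2.07 in MII oocytes, 25.3% ± 2.53 in zygotes and 28.6% ± 3.93 in 2-cell embryos (SD, n = 2 each). In 8-cell embryos the share was 7.91% ± 0.799 and in blastocysts 5.43% ± 2.38. Between the phases, the difference did not pass the test (22.5% ± 2.64 against 14.0% ± 11.6, n = 6 each, exact permutation p = 0.0909, adjusted p = 0.0909 over 3 annotation classes). The unadjusted exact permutation p was 0.0216 without 2-cell replicate 1 and 0.0433 without replicate 2. Without any other single library it was 0.106 to 0.190, and with whole stages permuted it was 0.4. Peaks over protein-coding genes made up 60.8% to 74.4% per library up to the 2-cell stage and 86.1% to 92.4% in the 8-cell and blastocyst libraries. Their share did not pass the test between the phases either (70.7% ± 2.90 against 80.4% ± 13.1, n = 6 each, exact permutation, adjusted p = 0.0909), with an unadjusted exact permutation p of 0.0195 without 2-cell replicate 1 and 0.0411 without replicate 2. Without any other single library that p was 0.102 to 0.188. In genes longer than 10000 bp, 20.8% to 35.9% of peaks per library lay within 2000 bp of a gene end, against 9.87% to 12.4% for uniform placement.

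**Figure D2:**
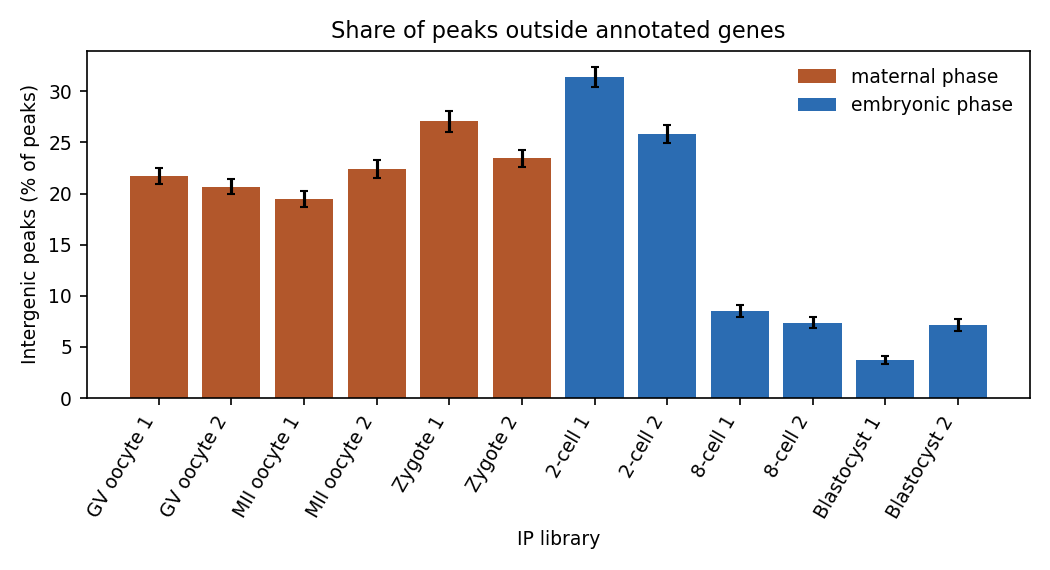
Share of peaks (percent, with 95% exact binomial intervals that cover counting error only) whose midpoint lies outside annotated genes, for each of the 12 immunoprecipitated libraries, coloured by phase. The 4 libraries of 8-cell embryos and blastocysts lie between 3.74% and 8.47%, and the other 8 between 19.5% and 31.4%.

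Of the genes marked in all 6 maternal libraries and in none of the embryonic phase, the 12 highest-ranking included Rgs2 (a regulator of G-protein signalling), Obox2 (an oocyte-specific homeobox gene), Nlrp14 and Nlrp4b (members of a gene family expressed in oocytes), Gtsf1 (a retrotransposon-silencing factor of germ cells), Gja4 (connexin 37, of the channels between oocyte and granulosa cells) and Bmpr1b (a receptor for bone morphogenetic proteins). Bcl2l10 (of the Bcl-2 family), Tent5b, Camta1 (a calmodulin-binding transcription activator), Umodl1 and Zc3h6 completed this group. The best peak of Rgs2, in MII oocyte replicate 1, lay at chromosome 1, 144001415 to 144001917, inside the gene, and that of Gja4, in GV oocyte replicate 2, at chromosome 4, 127311578 to 127312344, 540 bp from a gene end, with 10.7-fold enrichment. Genes with peaks in all 6 embryonic libraries and no maternal one were led by Pramel7 and Pramel6 (PRAME-like genes of the early embryo), Elovl6 (a fatty acid elongase), Rpl10l (a ribosomal protein retrogene), Spry2 (an antagonist of receptor tyrosine kinase signalling), Rbis, Kbtbd2, Purb, Spic (an ETS transcription factor), Klf9 (a Krüppel-like factor), Calcoco2 (an autophagy receptor) and Trim43a. The best Pramel7 peak, in 8-cell replicate 1, lay at chromosome 2, 87489288 to 87490174, with 10.4-fold enrichment, and that of Spry2, in blastocyst replicate 1, at chromosome 14, 105896626 to 105897057, 22 bp from a gene end. Obox2, Pramel6, Pramel7 and Trim43a have close relatives, so their reads can be shared with other copies.

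Of 2310 protein-coding genes marked in 5 to 7 libraries, 647 were marked more often in the maternal phase and 498 in the embryonic phase (Fisher's exact test per gene, Benjamini-Hochberg adjusted p at most 0.0306). Of these, 274 were marked in all 6 maternal libraries and no embryonic one, and 245 the other way round (each Fisher's exact p = 0.00216, adjusted p = 0.00963). The genes called for the maternal phase were longer, with a median of 49571 bp against 20296 bp. With the same number of peaks per library the counts were nearly equal, 515 maternal and 510 embryonic. Restricted to peaks with a score at or above the median of all lists, the test called 711 maternal and 190 embryonic genes. That cut-off lay below the median score of each maternal list and above that of each embryonic list, so it removes more embryonic peaks. Among genes under 50000 bp the order was reversed, with 325 maternal and 399 embryonic calls, as it was from peaks within 2000 bp of a gene end (289 and 321), both added after seeing the data. With peaks at or above the median fold of their own library, also added then, it called 344 maternal and 225 embryonic genes. Without 2-cell replicate 1 it called 909 maternal and 815 embryonic genes, and without 2-cell replicate 2 it called 901 and 769. With 1 library left out more genes can reach the threshold and are tested (3468 and 3475 here). Leaving out any 1 library gave more calls than the main test, so these rises are not due to the 2-cell libraries alone. Compared as 4 oocyte libraries against 8 embryo libraries, Fisher's exact test called 0 genes after adjustment and 244 at an unadjusted p under 0.05. Replicates of a stage are not independent samples of a phase, so these p-values describe the 12 libraries.

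Step by step, the marked genes changed most around the 2-cell stage. From zygote to 2-cell, 978 genes were gained (marked in both later libraries and neither earlier one) and 786 were lost, while the 2 crossed splits of the same 4 libraries gave 25 to 199. The gained genes with the strongest peaks were Dnajb9 (an endoplasmic reticulum chaperone), Ppp1r15a (a stress-induced phosphatase subunit), Larp1 (a translational regulator) and Klhl11. All 4 had been marked in both GV oocyte libraries, and 373 of the 978 gained genes in at least 1 oocyte library, so a gain is not always a first mark. The lost ones were Rgs2, Obox2, Dnajb4 (a heat shock protein) and Rbbp7 (a histone-binding protein). From 2-cell to 8-cell, 1080 genes were gained, led by Tardbp (an RNA-binding protein), Tmem41b, Lrpap1 and Pramel4, and 561 were lost, led by Slco3a1, Spry4, Ppp1cb (a protein phosphatase 1 catalytic subunit) and Pld5, against 68 to 149 in the crossed splits. Of these 1080 genes, 592 had been marked in at least 1 library before the 2-cell stage, Tardbp in all 6 maternal ones. From 8-cell to blastocyst, 474 genes were gained, among them B3gnt5 (a glycosyltransferase), Dppa1, Id2 and Tfap2a (the last a transcription factor of trophectoderm). Of these 474 genes, 287 had been marked in at least 1 library before the 8-cell stage, Tfap2a in 4 maternal ones. The 425 genes lost at this step included Rpl34, Rps29, Rps3a1 (ribosomal proteins) and Foxe1, against 69 to 219 in the crossed splits. From GV to MII, 866 genes were lost (among them Fbxo11, Ube2g1, G3bp2 and Rhpn2) and 330 gained (among them Ywhaz, Fabp5, Tpd52 and Atp6v1e1), against 12 to 117. GV oocytes had the longest lists (11456 ± 711 peaks, SD, n = 2), and with the same number of peaks per library 631 genes were lost from GV to MII and 816 from zygote to 2-cell. From MII to zygote, 66 genes were gained (led by Parp12, Rbm38, Ldhb and Ptpn2) and 251 lost (led by Upf1, a factor of nonsense-mediated decay, Tbc1d14, Kif18a and Yeats4), within the 39 to 392 of the crossed splits. With 2 libraries against 2, no p under 0.333 can be reached. A count needs fewer libraries, and is larger, when 1 is left out: 1657 genes were gained from zygote to 2-cell without 2-cell replicate 1.

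**Figure D3:**
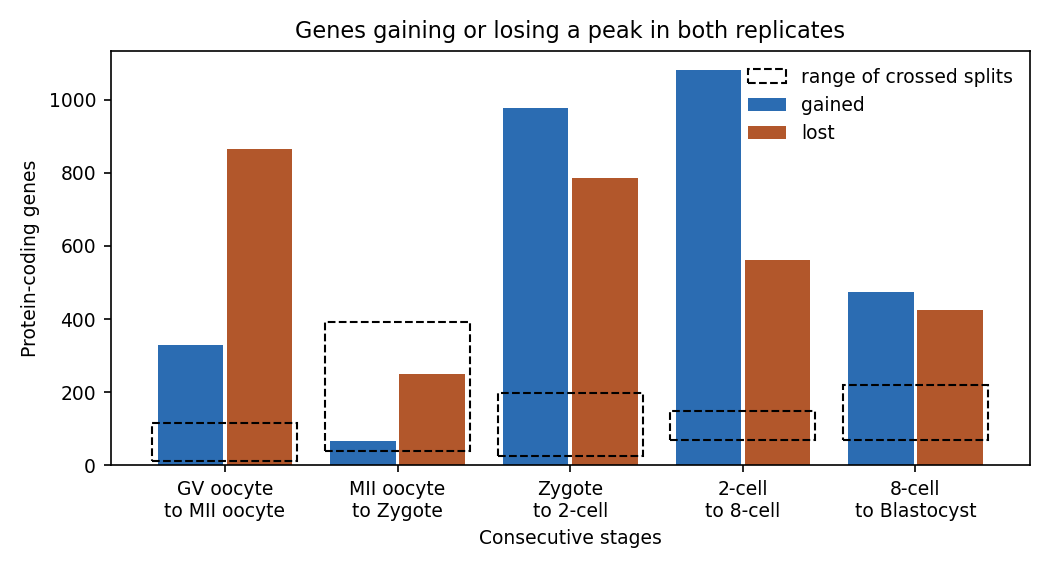
Number of protein-coding genes gained (marked in both libraries of the later stage and neither of the earlier) and lost at each of the 5 steps of development, with dashed boxes for the range of the crossed splits of the same 4 libraries. Gains were highest from 2-cell to 8-cell (1080); losses were highest from GV to MII oocytes (866) with all peaks, but from zygote to 2-cell (816 against 631) with the same number of peaks per library, which is not drawn.

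Oocyte-specific genes were marked more often in the maternal phase. Of the 25 such genes listed, 11 had no peak in any library. Of the 14 with a peak in any library, 9.67 ± 1.21 were marked per maternal library and 1.0 ± 1.55 per embryonic library (SD, n = 6 each). After subtraction of each library's share over all genes, the difference was 64.1 percentage points (exact permutation, adjusted p = 0.00703). It was 22.5 points with peaks at or above the median fold of their own library, added after seeing the data (adjusted exact permutation p = 0.0201). Nlrp14 and Oas1e were marked in 6 maternal and 0 embryonic libraries, Nlrp4f and Bmp15 (an oocyte growth factor) in 6 and 1. The list tested 6 genes one by one and called 5 for the maternal phase, over all genes and adjusted over the list alone. The maternal-effect genes, needed in the egg for early cleavage, did not pass the test (11.2 ± 1.17 against 8.17 ± 2.14 of 19, 18.0 points, exact permutation, adjusted p = 0.0563). Bnc1 was marked in 6 maternal and 0 embryonic libraries, and Dnmt1, Nlrp5 and Zar1l were still marked in both 2-cell libraries. That list passed with the same number of peaks per library (23.1 points, adjusted exact permutation p = 0.0188) and without 2-cell replicate 1 (0.0188) or replicate 2 (0.0469). Genes of maternal mRNA decay and translational control (6.53 points, adjusted exact permutation p = 0.0921, and 0.0338 without 8-cell replicate 2) held Eif4e1b and Pabpn1l with 6 maternal and 0 embryonic libraries, Ybx2 with 5 and 0, and Tut4 with 0 and 6. Meiosis regulators also went both ways (5.01 points, adjusted exact permutation p = 0.298): Mos, Wee2 and Fbxo43 had 6 maternal and 0 embryonic libraries, and Cdc14b had 0 and 6.

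Genes of the 2-cell stage and zygotic genome activation were marked more often in the embryonic phase. Of 24 such genes, 20 and 19 were marked in the 2-cell libraries, 13 and 16 in the 8-cell libraries, 8 and 6 in the blastocyst libraries, and 2 to 6 in each maternal library (difference of -37.4 points, maternal minus embryonic, exact permutation, adjusted p = 0.00703). Ubtfl1, Tdpoz1 and Tdpoz2 were marked in all 6 embryonic libraries and no maternal one, and Obox6 in 5 and 0. Tdpoz and Obox genes lie in families of near copies, so the member is uncertain. Of 19 pluripotency genes, 6.5 ± 1.38 were marked per maternal and 13 ± 2.53 per embryonic library (-32.0 points, exact permutation, adjusted p = 0.00703). Klf5 and Zfp42 were marked in 0 maternal and 6 embryonic libraries, Tbx3 in 1 and 6, and Fgf4 in 0 and 5.

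Genes of the trophectoderm and primitive endoderm, lineages of the blastocyst, were marked more often in the embryonic phase, mainly through its 8-cell and blastocyst libraries. Both 8-cell and both blastocyst libraries, and no other, marked the trophectoderm genes Cdx2, Eomes and Lrp2, and Tead4 was marked in all 6 embryonic libraries and no maternal one. Tfap2c, Tjp1 and Yap1 were marked in all 12 libraries, and Gata3 in 6 maternal and 4 embryonic ones; these 4 were named after their values were seen. The trophectoderm list had 7.17 ± 2.23 of 22 members marked per maternal and 14 ± 5.97 per embryonic library (-28.8 points, exact permutation, adjusted p = 0.0375), with 5 marked in both 2-cell libraries and 18 in both blastocyst libraries. That call was lost with the same number of peaks per library (-26.3 points, adjusted exact permutation p = 0.0506) and with a replicate block (-28.8 points, 0.0578). It was also lost without GV oocyte replicate 2 (-29.5 points, adjusted exact permutation p = 0.0528), MII oocyte replicate 1 (-27.2 points, 0.0625), MII oocyte replicate 2 (-28.6 points, 0.0563) or zygote replicate 2 (-27.9 points, 0.0633), so the difference itself moved little. In the primitive endoderm list (1.5 ± 0.837 against 5.67 ± 2.88 of 11, -35.6 points, exact permutation, adjusted p = 0.00938), Gata6, Pdgfra and Fgfr1 were marked in the same 4 libraries, and Gata4 in both 2-cell and 2 later ones. The 2-cell libraries marked 2 and 3 members of this list, the maternal ones 1 to 3, and the 8-cell and blastocyst ones 6 to 10. With peaks at or above the median fold of their own library, added after seeing the data, the list no longer passed (-15.5 points, adjusted exact permutation p = 0.174). Chromatin and DNA methylation regulators differed by -14.9 points (19.2 ± 3.43 against 25.2 ± 4.67 of 35, exact permutation, adjusted p = 0.0161). Here too the 2-cell libraries (21 and 18) lay within the maternal range (14 to 23), and the 8-cell and blastocyst libraries marked 26 to 30. The histone demethylase genes Kdm5a and Kdm5b were marked in 0 maternal and 6 embryonic libraries, Tet1 in 2 and 6, and Dot1l in 0 and 4.

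Transcripts of the m6A machinery carried peaks themselves. Wtap, Virma, Rbm15, Rbm15b and Zc3h13, partners of the methyltransferase, were marked in all 12 libraries, Cbll1 in 0 maternal and 6 embryonic ones, Mettl14 in 1 and 0, and Mettl3 in none. The writer list differed by -9.67 points (5.17 ± 0.408 against 6 of 7 members, exact permutation, adjusted p = 0.0375), which with all peaks rests on Cbll1 and was lost when any of 9 of the 12 libraries was left out (adjusted exact permutation p up to 0.0719). With peaks at or above the median fold of their own library, added after seeing the data, it was larger (-32.6 points, adjusted exact permutation p = 0.00938). From peaks within 2000 bp of a gene end only, also added then, the difference reversed and did not pass (5.25 points, adjusted exact permutation p = 0.626). The list of readers and erasers did not differ (8 ± 1.79 against 8.33 ± 1.75 of 13, -0.332 points, exact permutation, adjusted p = 0.957). Ythdc2 was marked in 6 maternal and 2 embryonic libraries, Ythdf1 in 2 and 6, Hnrnpc in 2 and 5, and Hnrnpa2b1 in 4 and 3.

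Cytosolic ribosomal protein genes were marked more often in the embryonic phase. Of 52 members, 6.67 ± 2.25 were marked per maternal and 27.2 ± 15.0 per embryonic library (-37.2 points, exact permutation, adjusted p = 0.00938). The 2-cell replicates differed, with 15 and 43 members marked, while the 8-cell libraries had 39 and 40 and the blastocyst libraries 16 and 10. These peaks had low enrichment: in the 8-cell libraries their median fold was 3.51 and 2.91, against 6.12 and 5.68 over all peaks of these libraries. With peaks at or above the median fold of their own library, a limit added after seeing the data, the 8-cell libraries marked 4 and 5 members, 2-cell replicate 2 marked 11 and the maternal libraries 0 to 4, and the list no longer passed (-10.0 points, adjusted exact permutation p = 0.521). Rpl23a was marked in 0 maternal and 6 embryonic libraries, Rpl41 in 1 and 6, and Rpl4 and Rps7 in 0 and 5. Ribosomal protein genes have many processed copies in the genome, so reads can be shared with them. Markers of cumulus and granulosa cells, the somatic cells around the oocyte, differed the other way (2.83 ± 1.47 against 0.5 ± 0.548 of 7, 35.6 points, exact permutation, adjusted p = 0.00703). Kitl and Cyp11a1 were marked in 5 maternal and 0 embryonic libraries, Inhba in 4 and 0, and Cyp19a1 in 2 and 0. The remaining members, named after their values were seen, were Has2 (1 and 0), Amhr2 (0 and 1) and Inhbb (0 and 2). Of the 22 markers listed, 15 had no peak in any library. Per library, 4 and 4 of these markers were marked in GV oocytes, 3 and 4 in MII oocytes and 1 and 1 in zygotes, where 11 and 9 oocyte-specific genes were marked. Both 8-cell libraries and blastocyst replicate 2 marked 1 each. Of the sperm transcripts, too few for a test, Prm2 was marked in 6 maternal and 0 embryonic libraries, GV oocytes included, and Odf2 in 2 and 1.

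These list tests are lenient, since 37.3% of 1000 random lists of 20 background genes reached an unadjusted exact permutation p under 0.05. Against 10000 random lists of the same size matched on the number of marked libraries, an addition made after seeing the data, 8 of the 13 lists lay outside the central 95%: oocyte-specific, zygotic genome activation, pluripotency, trophectoderm, primitive endoderm, chromatin, cumulus and granulosa, and ribosomal protein genes. The m6A writer list did not, with 21.2% of random lists as far on the same side. From peaks within 2000 bp of a gene end only, also added later, the trophectoderm (-23.6 points, adjusted exact permutation p = 0.0528), ribosomal protein (-33.0 points, 0.0528) and cumulus and granulosa (19.1 points, 0.0907) lists no longer passed. Nor did the m6A writer list, whose difference reversed (5.25 points, adjusted exact permutation p = 0.626), while the decay and translation list passed (27.2 points, 0.00938). With peaks at or above the median fold of their own library, the primitive endoderm list no longer passed either (-15.5 points, adjusted exact permutation p = 0.174). The pluripotency (-19.1 points, adjusted exact permutation p = 0.00938), chromatin (-23.9 points, 0.0201) and cumulus and granulosa (53.5 points, 0.00938) lists still passed. The decay and translation list (-10.3 points, adjusted exact permutation p = 0.0281) and the meiosis list (-20.2 points, 0.0201) then passed in the embryonic direction, opposite to their difference with all peaks. With the 4 oocyte libraries against the 8 embryo libraries, only the cumulus and granulosa list passed (41.3 points, adjusted exact permutation p = 0.0263). The oocyte-specific list, with the same difference, did not (adjusted exact permutation p = 0.105). With whole stages permuted none could, the smallest p being 0.1.

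**Figure D4:**
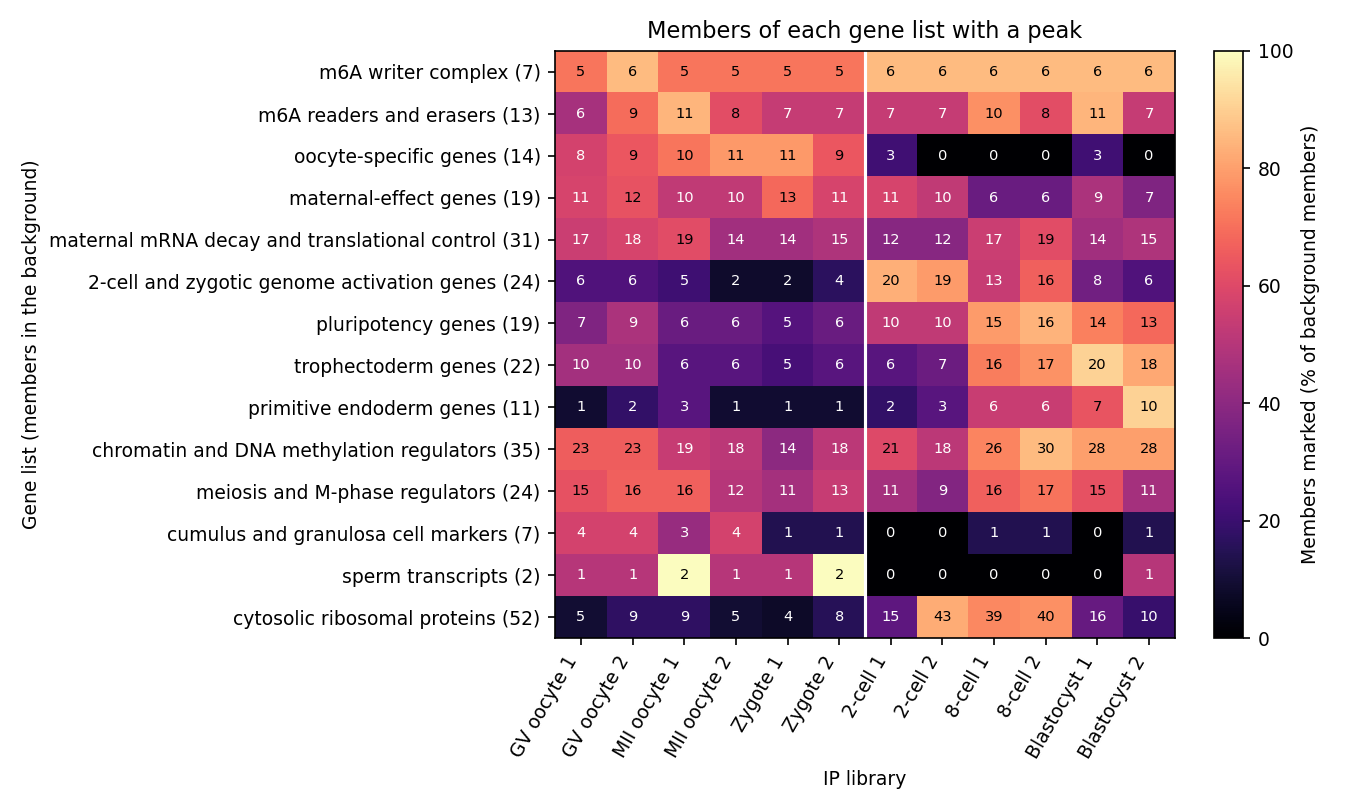
Members of each of the 14 gene lists marked in each of the 12 immunoprecipitated libraries, as counts in the cells and as a colour scale in percent of the members with a peak in any library, with a white line between the phases. Of 14 oocyte-specific genes, 8 to 11 are marked per maternal and 0 to 3 per embryonic library, zygotic genome activation genes have their highest counts in 2-cell libraries (20 and 19 of 24, then 13 and 16 in 8-cell libraries), and ribosomal protein genes in 2-cell replicate 2 (43 of 52) and both 8-cell libraries (39 and 40).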

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

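Chosen only after the result was seen were the tests of the number of intergenic peaks, of intergenic shares among strong peaks, of low-fold peaks in ribosomal protein genes, and of gene-end peaks for each phase on its own. Over 44 groups of 6 values, chance alone would mark about 1 in 20 as having a value far from the rest.

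GV oocyte replicate 2 marked 6 members of the m6A writer complex, against 5 in each other maternal library. Blastocyst replicate 2 marked 1 sperm transcript, against 0 in each other embryonic library. The 4 oocyte libraries held 22 peaks on chromosome Y (3 to 7 each), where 3 in all was the limit for this flag. Oocytes are female cells, so these peaks cannot be read as transcripts of a Y chromosome. The 2-cell libraries held 33 and 35, and the source of the peaks was not tested.

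Intergenic peaks were scarce in the 8-cell and blastocyst libraries. List length is argued against, since with the same number of top peaks per library the 4 late libraries had at most 7.23% and the other 8 at least 18.6%, and dilution by more genic peaks is argued against by counts of at most 746 against at least 1870. The planned test of weak calls left them open, since the lowest median rank of intergenic peaks in an earlier library was at percentile 45.2, neither under 25 nor above 50; among peaks with a score at or above the median of all lists, a test added later, the shares were at most 4.67% against at least 18.6%. A difference between the stages themselves stays open and untested. So do transcribed repeats, unannotated genes and genomic DNA left in the libraries, for which no test could be run here.

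Ribosomal protein genes were marked in 2-cell replicate 2 and both 8-cell libraries. Small nucleolar RNAs inside these genes touched 11.5% of the peaks, too few to account for them, and with equal list lengths the lowest of the 3 libraries marked 37 members against at most 15 elsewhere. Low-fold calls on abundant transcripts stay a candidate explanation: with peaks at or above their own library's median fold, the 8-cell libraries marked 4 and 5 members and the other 9 libraries at most 4, although 2-cell replicate 2 still marked 11. RNA of 8-cell embryos in 2-cell replicate 2 was examined with the 100 strongest 8-cell genes outside the list. That replicate marked 82% of them and replicate 1 marked 70%, against 82.7% and 28.8% of the ribosomal protein genes. By the rule written beforehand, so small a gap outside the list argues against this explanation. The rule did not foresee that replicate 1, already at 70%, leaves too little room for the test. The peak set of 2-cell replicate 2 also overlapped those of the 8-cell libraries more (0.255 and 0.258) than that of replicate 1 did (0.194 and 0.194). RNA of 8-cell embryos in replicate 2 therefore cannot be told apart from a difference between the pools. Expression was not measured here, and a difference between stages stays open and untested.

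The 1145 genes called between the phases exceeded those of other splits of the libraries: 1 of 100 splits, the real one, gave as many, with 0 in the highest other. With replicates kept together, 1 of 10 splits gave as many and the highest other gave 0, but 10 splits are too few for a share under 0.05; because adjustment can return 0, the unadjusted counts are also given, 1145 against at most 262 among the drawn splits and 290 among the stage splits. List length is argued against, with 67.2% of the calls made again with equal lists. From peaks near gene ends alone, 46.1% of the calls were made again, 58.2% of the embryonic ones and 36.8% of the maternal ones, so peaks deep inside gene bodies do not account for most embryonic calls and may contribute to maternal ones. A change in which genes are expressed stays open, since the inputs were not analysed here.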

How the results depend on the processing

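Of 532 results recomputed under an alternative, 430 kept their direction and side of the threshold (or lay within 1.5 times the main count), 38 became weaker, 16 stronger, 34 moved and 14 reversed; unknown read depth limits all of them. The cause was not tested unless given. The planned motif alternatives were not run. Alternatives added after seeing the data were those on gene ends, genes under 50000 bp, peaks inside 1 gene only, and peaks at or above the median fold of their own library.

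With a score at or above the median of all lists, the peaks per library differed by 2577 and 190 embryonic-phase genes were called, with 711 maternal ones. This cut-off removes more embryonic peaks, since it lay above the median score of each embryonic list and below that of each maternal one. Oocytes against embryos called 0 maternal and 0 embryonic genes (Fisher's exact test; 244 at an unadjusted p under 0.05) and 1 gene list, that of cumulus and granulosa markers (41.3 points, adjusted exact permutation p = 0.0263). With stages permuted 3 against 3, 0 lists could pass. Genes under 50000 bp gave 325 maternal and 399 embryonic calls and peaks near gene ends 289 and 321, from fewer genes tested, so that in both the order of maternal over embryonic calls was reversed. With the same number of peaks per library, 515 maternal and 510 embryonic genes were called, 143 genes were lost from MII oocyte to zygote, losses were highest from zygote to 2-cell (816, against 631 from GV to MII), the trophectoderm list no longer passed (-26.3 points, adjusted exact permutation p = 0.0506) and the maternal-effect list did (23.1 points, 0.0188). The difference for m6A readers and erasers, near 0, changed sign with the same number of peaks (2.74), oocytes against embryos (0.518), peaks inside 1 gene (0.354) and peaks near gene ends (3.27). That for the writers became 5.25 near gene ends (adjusted exact permutation p = 0.626). With peaks at or above the median fold of their own library, 344 maternal and 225 embryonic genes were called, and the difference became 0.169 for readers and erasers, -10.3 for decay and translation, -20.2 for meiosis, -10.0 for ribosomal proteins (adjusted exact permutation p = 0.521), -15.5 for primitive endoderm (0.174), -32.6 for the writers (0.00938) and 22.5 for oocyte-specific genes (0.0201).

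Leaving out 1 library in turn gave differences of 539 to 1548 for peaks per library, -410 to 32.3 for marked genes per library (reversed without zygote replicate 1), -13.7 to -7.34 for the protein-coding share, 0.916 to 1.71 for other genes only, 6.43 to 12.0 for the intergenic share, and -4.38 to 3.81 for readers and erasers. Maternal-phase calls ranged from 675 to 909 and embryonic-phase calls from 501 to 815, out of more genes tested (3037 to 3505, against 2310 in the main test). Genes gained and lost rest on 3 libraries then and are more by construction: GV to MII 391 to 687 and 1005 to 1401, MII to zygote 114 to 371 and 317 to 952, zygote to 2-cell 1009 to 1657 and 950 to 1563, 2-cell to 8-cell 1345 to 1738 and 679 to 1006, and 8-cell to blastocyst 619 to 1038 and 562 to 1027.

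Same-numbered replicates did not deviate together (correlations of -0.165 to 0.0249 over 15 pairs of stages), so no effect shared by replicate number was seen. Whether they were collected or processed together cannot be told from this. With a replicate block, 647 maternal-phase and 498 embryonic-phase genes were called, the same 1145 genes, and the writer and trophectoderm lists had an adjusted exact permutation p of 0.0578.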

Other observations

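Genes marked in both replicates of a single stage and in no other library were most frequent at the ends of the series: 185 in GV oocytes, 187 in blastocysts, 138 in 8-cell embryos and 129 in 2-cell embryos, but 24 in MII oocytes and 13 in zygotes. The same count for 60 pairs of libraries from different stages had a median of 6 and a maximum of 69. GV oocytes alone marked Oas1d and Ccno (a cyclin-like gene), 2-cell embryos Pld5, 8-cell embryos Alppl2 (an alkaline phosphatase of the early embryo), and blastocysts B3gnt5, F2rl1 (a protease-activated receptor), Vgll3 and Bcl9l (a Wnt cofactor). MII oocytes alone marked Ska1 (a kinetochore protein) and Ezh2 (a histone methyltransferase). Apart from Pld5 and B3gnt5, these genes were chosen after their values were seen.

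Prm2, which encodes a protamine of sperm chromatin, was marked in GV and MII oocytes as well as in zygotes, with a best peak at chromosome 16, 10791743 to 10792092, in zygote replicate 2. Of the 15 sperm transcripts listed, 13 had no peak in any library.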
